A study of Homo sapiens with 6 samples.

How the data were processed

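The series measured messenger RNA of human primary B cell populations on 6 Lymphochip arrays, glass arrays spotted with cDNA clones chosen for lymphocyte biology. Per the labels' protocols, polyA+ RNA of a B cell population was labelled with Cy5 by reverse transcription, and a pool of polyA+ RNA from several human cell lines, labelled with Cy3, served as the reference on every array. The 3 groups were mature B cells of bone marrow, plasma cells of bone marrow and naive B cells of blood, with 2 arrays each. The design text says that labelling and hybridisation were done in duplicate and names no separate donors or extracts. The p-values therefore compare RNA preparations against the spread between 2 hybridisations, which may be technical, and do not measure the spread between people.

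The values used were 1 table of log2 ratios as deposited, with 15152 array elements in rows and the 6 arrays in columns. The log base was taken from the values: the largest absolute value was 15.247, above the natural log of the highest 16-bit ratio (11.1) and below its log2 of 16. Scanner, background correction, spot filter and normalization are not given in the sources used here, and neither is the reason for empty cells. Medians of the deposited columns lay between 0.0085 and 0.215, so the exact centring by the authors stays unknown. The direction was taken as Cy5 over Cy3, which the dye labels make likely but the table does not state. As a check, 10 genes were fixed before the data were examined, of which 9 were measured, and all 9 lay in the direction known for plasma cells against B cells. That check uses textbook genes, so their direction in the results is not independent of it. The precision of every value is limited by the number of arrays.

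Gene names came from the platform annotation paired with the elements: 10165 elements had 1 gene symbol, 4 had several and 4983 had none, and 4603 genes were named. Elements of sex-linked genes that are never reported (19) were left out. Elements with a value on all 6 arrays were kept, 9536 in number, of which 6913 had 1 symbol. Each array was centred on its median over these elements. Elements of 1 gene were then averaged per array, which gave 3487 genes, 1762 of them from over 1 element, beside 2623 unnamed elements tested on their own and counted apart. Elements of a gene can disagree in sign or in size. Disagreement in sign is stated for the named genes past the threshold, and the SE of an averaged value does not hold the spread in size. Clone annotation was not checked against clone sequences, so a gene measured by 1 or 2 elements is named only as far as that annotation holds. Clones of close relatives can hybridise to each other's RNA, so values of HLA, defensin, globin, chemokine and immunoglobulin genes are uncertain as to the family member.

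Group means were fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual degrees of freedom, 2.48 prior degrees of freedom), and the 3 differences between groups were tested two-sided. Benjamini-Hochberg adjustment ran over all rows of a comparison, with a threshold of 0.05. Known changes were planted in 200 genes of simulated data with noise at the observed SD of each row, a setting that may differ from the real comparisons. The share recovered at a log2 change of 4 was 54.5% for plasma cells against mature B cells, 66.7% for plasma cells against naive B cells and 56.1% for mature against naive B cells. At a log2 change of 1 it was 0% in each.

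Before the data were examined, 31 gene lists were fixed, 20 of processes or gene classes and 11 of markers of cell types that the samples could hold. The 30 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over all 90 tests of lists and comparisons, and again with an estimated correlation and with fry. Of the 28 list tests past the threshold, 0 stayed past it with the estimated correlation. That estimate was below the preset for several lists, among them plasma cell genes (-0.025) and the unfolded protein response (-0.025). A higher correlation therefore did not weaken those tests. With an estimated correlation camera uses only the 3 residual degrees of freedom, which limits how low its p can be. For plasma cell genes in plasma against naive B cells the camera p went from 2.85e-12 to 0.00454, the lowest of the 90 tests. The estimate for MHC class II genes, 0.146, was above the preset and may have weakened that test too. An adjusted p of 0.172 with an estimated correlation therefore cannot tell an unchanged list from too few arrays. Counts of list members are given over all rows tested and adjusted over the list alone. The ribosomal, oxidative phosphorylation and proteasome lists were filled by the start of the symbol, from protein-coding genes only and without the ribosomal protein kinases.

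Genes named in the text follow a rule fixed beforehand, though not every gene it selects is named. Per comparison, it selects the 10 largest increases and the 10 largest decreases among genes past the threshold whose differences between single arrays share 1 sign, and the 3 members of each list with the largest absolute difference. A fixed set was added: PRDM1, XBP1, IRF4, PAX5, BCL6, CIITA, SDC1, MS4A1, MYC, TNFRSF17 and CD38. Another gene of that set is not reported here. Other list members named below were chosen after their values were seen.

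Alternatives were the deposited values without centring, quantile normalization, rows with at least 1 value per group, single elements, only the 4 arrays compared, the repeat number as a block, each array left out in turn, a minimum difference, a rule of size without a test, and limma treat. Array weights and ratios limited to 6 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.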

Results

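The arrays compared 2 kinds of B cell that have not yet become antibody-secreting cells, mature B cells of bone marrow and naive B cells of blood, with plasma cells of bone marrow, the cells that secrete antibody. Every value is a log2 ratio of a population's RNA to the same reference pool, so differences between groups are differences of such ratios. Between 11274 and 14601 of the 15152 elements had a value on an array. The arrays of repeat 2 lacked 19.3% to 25.6% of the values, and those of repeat 1 lacked 3.64% to 6.28%. Across rows, which are not independent replicates, the 2 arrays of a group correlated with Pearson's r of 0.890 for plasma cells, 0.835 for mature B cells and 0.876 for naive B cells. The median absolute difference between duplicates was 0.46, 0.60 and 0.43 on the log2 scale. By SD the ratios of repeat 2 spread more in every group, with 2.71 against 1.82 for mature B cells, 2.41 against 2.08 for plasma cells and 2.38 against 2.04 for naive B cells. The interquartile range of plasma cells went the other way, with 2.29 in repeat 2 and 2.39 in repeat 1.

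Plasma cells differed from mature bone marrow B cells first by the loss of B cell identity transcripts. MS4A1, which encodes the surface antigen CD20, fell by 8.66 on the log2 scale (SE 0.83), from 2.25 ± 0.37 to -6.41 ± 1.68 (mean ± SD, n = 2 arrays per group). Its 5 elements ranged from -12.85 to -4.80, so the size of the fall is less certain than the SE of their average shows. TCL1A, a kinase co-activator, fell by 9.45 (SE 0.70), and PAX5, the transcription factor that maintains B cell identity, fell by 6.04 (SE 0.82). In the other direction XBP1, a transcription factor of the secretory programme, rose by 6.59 (SE 0.79) and SDC1, the plasma cell surface proteoglycan CD138, rose by 6.49 (SE 0.50). PRDM1, the repressor that drives plasma cell differentiation, rose by 2.77 (SE 0.39). In all, 214 genes passed the limma threshold, 119 higher and 95 lower in plasma cells, with 169 unnamed elements besides.

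**Figure D1:**
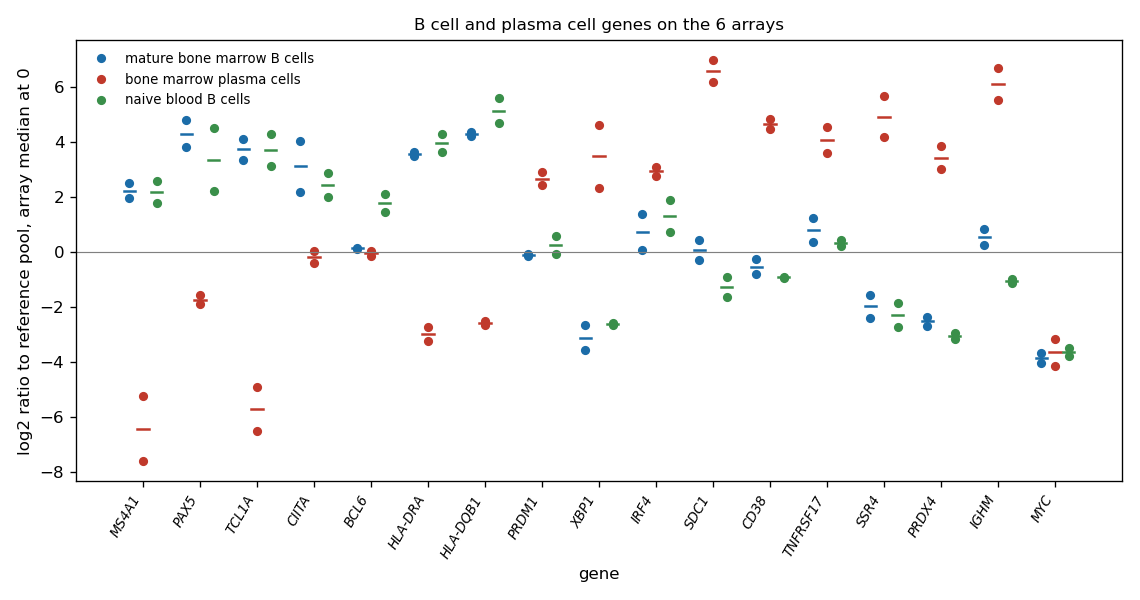
Log2 ratio to the reference pool (vertical axis, array median at 0) of 17 B cell and plasma cell genes (horizontal axis), with 1 point per array and a bar at the mean of the 2 arrays of each group. MS4A1 had means of 2.25 and 2.19 in the B cell groups and -6.41 in plasma cells, and MYC had means between -3.85 and -3.63 in all 3 groups.

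All 32 measured B cell surface and transcription factor genes had lower ratios in plasma cells than in mature B cells, with a median of -2.65. Of these 14 fell over all genes tested, and 27 fell when adjusted over the list alone (camera adjusted p = 9.21e-17, adjusted p = 0.172 with an estimated correlation). ETS1 and CR2, a complement receptor, were among them, with differences of -5.87 and -3.90. CD72 had a difference of -6.82 that did not pass (adjusted p = 0.0577). Of 10 genes of MHC class II presentation, the display of peptides to helper T cells, 7 fell, also 7 adjusted over the list alone, with a median of -3.82 (adjusted p = 9.60e-08, adjusted p = 0.172 with an estimated correlation). HLA-DQB1 fell by 6.86 (SE 0.42) and HLA-DRA fell by 6.56 (SE 0.39). CIITA, the class II transactivator, had a difference of -3.29 (adjusted p = 0.0577), and its 4 elements ranged from -7.51 to -0.05. Among naive B cell markers 4 of 15 fell and IGHM rose, with 7 lower and 1 higher adjusted over the list alone and a median of -1.60 (adjusted p = 0.0028, adjusted p = 0.172 with an estimated correlation), which was -0.74 with rows having at least 1 value per group. LYN, at -4.16, and VAV3, at -3.26, were among those that fell of 29 genes of B cell receptor signalling, 3 in number, and 10 lower and 2 higher were past the threshold adjusted over the list alone. That list had a median of -0.88 (adjusted p = 0.0028, adjusted p = 0.297 with an estimated correlation).

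Genes of the secretory pathway had higher ratios in plasma cells. Of 22 plasma cell genes 12 rose, and 16 rose adjusted over the list alone, with a median of 2.76 (adjusted p = 2.08e-10, adjusted p = 0.172 with an estimated correlation). Besides XBP1 and SDC1, BMP6 rose by 5.26, CD38 by 5.19 and TNFRSF17, the survival receptor BCMA, by 3.28. IRF4 had a difference of 2.21 that did not pass (adjusted p = 0.0974). Of 18 genes of the unfolded protein response and chaperones of the endoplasmic reticulum (ER), 6 rose and 15 rose adjusted over the list alone, with a median of 1.84 (adjusted p = 2.12e-09, adjusted p = 0.172 with an estimated correlation). MANF rose by 4.30, and CRELD2 had a difference of 4.60 that did not pass (adjusted p = 0.139). XBP1 is a member of both lists. SSR4, a subunit of the translocon-associated complex, rose by 6.90 (SE 0.66) and SSR3 by 5.80 (SE 0.35) among 19 genes of ER translocation and N-glycosylation. Of these 5 rose and 11 rose adjusted over the list alone, with a median of 1.46 (adjusted p = 0.000942, adjusted p = 0.172 with an estimated correlation). Only GOLGB1, at 3.47, passed among 13 genes of ER to Golgi transport, with 5 higher adjusted over the list alone and a median of 1.57 (adjusted p = 0.00101, adjusted p = 0.172 with an estimated correlation). LMAN1 at 4.22 (adjusted p = 0.0882) and COPE at 4.09 (adjusted p = 0.378) had larger differences in that list and did not pass, and the SD of COPE between the mature B cell arrays was 5.90. SLC1A4, an amino acid transporter, rose by 5.72 and AARS1, the alanyl-tRNA synthetase, by 3.87 among 16 genes of amino acid supply. In that list 6 rose, 11 adjusted over the list alone, with a median of 1.49 (adjusted p = 1.22e-05, adjusted p = 0.172 with an estimated correlation). Of 3 measured immunoglobulin genes, too few for a list test, IGHM rose by 5.58 and IGHA1 by 4.65, also when adjusted over the list alone, and IGHD had a difference of 0.34.

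Markers of other blood cells differed in the same comparison. Among 7 granulocyte precursor markers 4 rose, and 6 rose adjusted over the list alone, with a median of 4.54 (adjusted p = 2.02e-05, adjusted p = 0.172 with an estimated correlation), which was 2.80 without mature B cell replicate 1 and 2.25 with ratios limited to 6. CAMP, an antimicrobial peptide of neutrophil granules, rose by 7.31 (SE 0.52), DEFA1, a neutrophil defensin, by 5.96 (SE 0.90) and CTSG by 4.98. IL1B rose by 6.92 and CXCL8 by 3.26 among 13 monocyte and macrophage markers, with 6 higher and 1 lower adjusted over the list alone and a median of 1.16 (adjusted p = 0.00112, adjusted p = 0.172 with an estimated correlation). These differences stood beside those of the secretory lists on the same plasma cell arrays. Of 21 immediate early genes, which respond quickly to stimulation and to handling, NR4A3 at 7.24 and ATF3 at 6.96 were among the 4 that rose, and CD69, an activation marker, fell by 3.46, while JUND, at 4.38, did not pass (adjusted p = 0.355). Adjusted over the list alone 5 rose and 1 fell, with a median of 1.20 (adjusted p = 0.0147, adjusted p = 0.427 with an estimated correlation), and without mature B cell replicate 1 the list had an adjusted p of 0.0968, the highest over the alternatives at the preset correlation (lowest 0.00189). Its median was 0.78 without plasma cell replicate 2, 0.73 with rows having at least 1 value per group and 0.76 with ratios limited to 6. Among 28 ribosomal protein genes RPS25 fell by 2.18, with 0 past the threshold adjusted over the list alone and a median of -0.79 (adjusted p = 0.0202, adjusted p = 0.498 with an estimated correlation). Without plasma cell replicate 1 that list had an adjusted p of 0.133 and without mature B cell replicate 2 one of 0.186 and a median of -0.39, in a range from 0.00632 to 0.186 over the alternatives.

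Further large differences came from genes outside the lists described so far. The element annotated as COX15 rose by 7.31 (SE 0.61), and PRDX4, a peroxiredoxin of the ER, rose by 5.94 (SE 0.41). S1PR1, the receptor for sphingosine 1-phosphate, fell by 7.84 (SE 1.20). GPR18, RALGAPB, CYB561A3 and NIBAN3 also fell, with differences of -6.92, -6.45, -6.32 and -6.32. The clone annotation of COX15, CYB561A3 (1 element each) and RALGAPB (2 elements) was not checked against sequence, so the gene behind these values is uncertain. MYC had a difference of 0.21 and BCL6 of -0.18, and neither passed. Without mature B cell replicate 1 the count of 214 genes was 313, with 127 higher and 186 lower, so that the balance of directions turned, and without plasma cell replicate 2 it was 46, with 31 higher and 15 lower. It was 123 with only the 4 arrays compared, which is also the count without either naive B cell replicate, 90 without mature B cell replicate 2 and 113 without plasma cell replicate 1. With quantile normalization it was 342 and with single elements 351.

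Plasma cells differed from naive blood B cells in many of the same transcripts. MS4A1 fell by 8.60 (SE 0.83), TCL1A fell by 9.41 (SE 0.70) and HLA-DQB1 fell by 7.71 (SE 0.42). SDC1 rose by 7.84 (SE 0.50) and IGHM, the heavy chain of immunoglobulin M, by 7.17 (SE 0.50), from -1.05 ± 0.10 to 6.13 ± 0.83 (mean ± SD, n = 2 arrays per group). BCL6, a repressor of plasma cell differentiation, fell by 1.82 (adjusted p = 0.0442), though its 5 elements did not share 1 sign (highest 0.65). The limma threshold was passed by 274 genes, 137 higher and 137 lower in plasma cells, and by 226 unnamed elements.

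All 32 B cell surface and transcription factor genes again had lower ratios in plasma cells, with a median of -2.44. Of these 15 fell, and 26 fell adjusted over the list alone (adjusted p = 6.95e-15, adjusted p = 0.172 with an estimated correlation). PAX5 fell by 5.09 and ETS1 fell by 5.69. Of 10 MHC class II genes 7 fell and 8 fell adjusted over the list alone, with a median of -4.64 (adjusted p = 9.60e-08, adjusted p = 0.172 with an estimated correlation). HLA-DRA fell by 6.96 and HLA-DPA1 fell by 5.59, and CIITA had a difference of -2.61 (adjusted p = 0.0838). Naive B cell markers had 5 lower and 1 higher of 15, the same numbers adjusted over the list alone, and a median of -0.94 (adjusted p = 0.0163, adjusted p = 0.241 with an estimated correlation), which was -0.49 without naive B cell replicate 1. In B cell receptor signalling LYN, VAV3 and PRKCB were the 3 that fell, at -3.82, -3.46 and -3.27 (the 9 elements of PRKCB ranged from -7.11 to 0.24), with 6 lower and 2 higher adjusted over the list alone and a median of -0.65 (adjusted p = 0.0202, adjusted p = 0.372 with an estimated correlation). That list had an adjusted p of 0.102 without plasma cell replicate 1 and 0.0541 without naive B cell replicate 2, in a range from 0.00027 to 0.102 over the alternatives. Ribosomal protein genes had 2 of 28 lower, RPS25 at -2.45 and RPL22 at -2.29, also 2 adjusted over the list alone, and a median of -0.84 (adjusted p = 0.002, adjusted p = 0.376 with an estimated correlation). RPL37, at -2.82, did not pass (adjusted p = 0.105).

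Of 22 plasma cell genes 11 rose against naive B cells and 17 adjusted over the list alone, with a median of 2.49 (adjusted p = 8.54e-11, adjusted p = 0.172 with an estimated correlation). JCHAIN, the chain that joins secreted immunoglobulin subunits, rose by 6.45 (SE 0.32), ITGA6 by 6.28, XBP1 by 6.10, CD38 by 5.58, TNFRSF17 by 3.75 and PRDM1 by 2.41, and IRF4 had a difference of 1.61 (adjusted p = 0.172). Unfolded protein response genes had 6 of 18 higher and 15 adjusted over the list alone, with a median of 1.93 (adjusted p = 4.47e-08, adjusted p = 0.172 with an estimated correlation). CRELD2, at 5.80, did not pass (adjusted p = 0.0800). SSR4 rose by 7.20, SSR3 by 5.55 and RPN1 by 4.92 among the 7 of 19 ER translocation genes that rose, 10 adjusted over the list alone, with a median of 1.55 (adjusted p = 0.000908, adjusted p = 0.172 with an estimated correlation). ER to Golgi transport had 1 gene higher, GOLGB1 at 2.78, and 5 adjusted over the list alone, with a median of 1.24 (adjusted p = 0.0147, adjusted p = 0.241 with an estimated correlation). Without plasma cell replicate 1 that list had an adjusted p of 0.0794, and with rows having at least 1 value per group one of 0.0697 (range over the alternatives 0.00344 to 0.0794). LMAN1 had a difference of 3.10 (adjusted p = 0.154) and SEC23B of 2.24 (adjusted p = 0.0754). Amino acid supply genes had 4 of 16 higher and 7 adjusted over the list alone, with a median of 0.98 (adjusted p = 0.000369, adjusted p = 0.172 with an estimated correlation), which was 0.59 with rows having at least 1 value per group. IGHA1 rose by 6.03, so that 2 of 3 immunoglobulin genes rose, also adjusted over the list alone. IGLL1 rose by 7.09 and BMS1P20 by 8.31. IGLL1 shares sequence with lambda light chain genes and BMS1P20 lies among lambda variable segments in the reference gene table (GRCh38.p14), so either element may report light chain RNA.

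**Figure D2:**
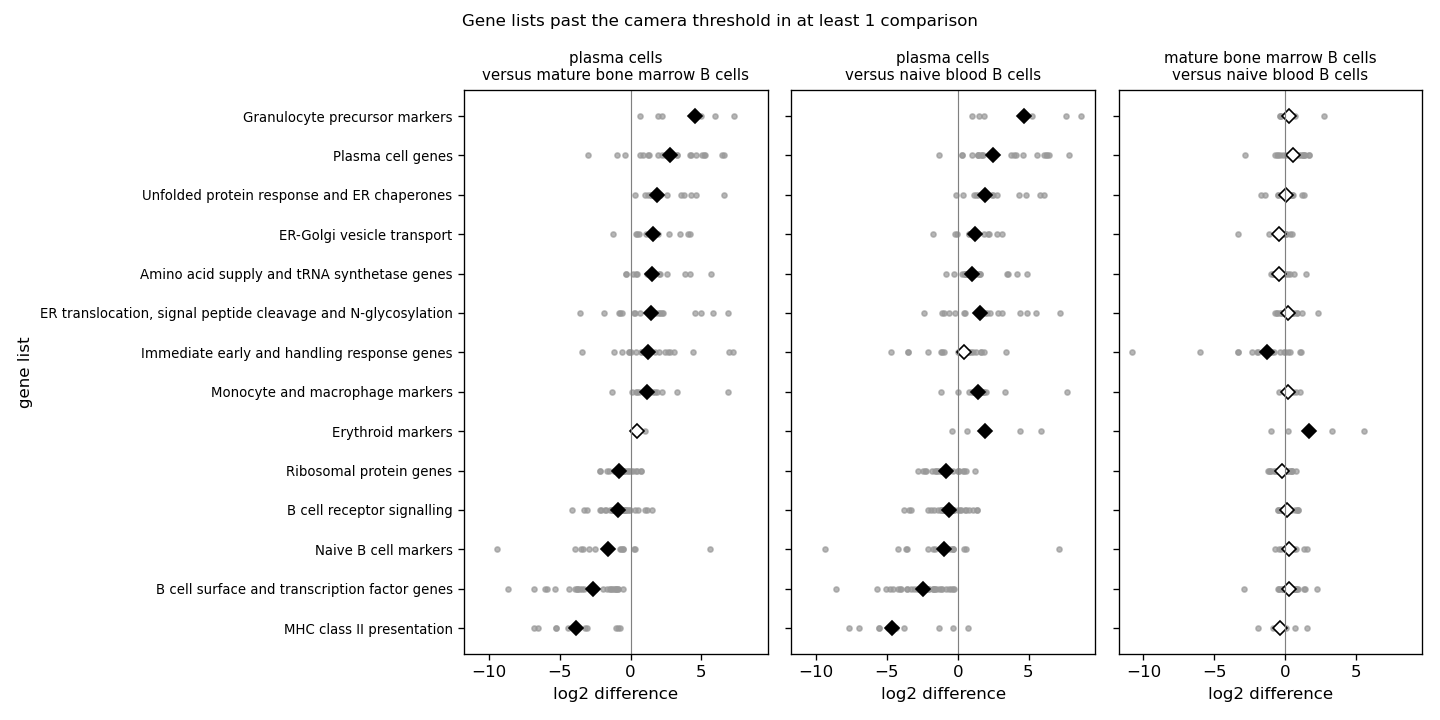
Log2 difference of each measured member (grey points) and list median (diamonds, filled where the camera adjusted p at the preset correlation was below 0.05) for the 14 lists past the threshold in at least 1 comparison, with 1 panel per comparison. Medians of the MHC class II list lay at -3.82, -4.64 and -0.36, and those of plasma cell genes at 2.76, 2.49 and 0.59.

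Granulocyte precursor markers had 3 of 7 higher in plasma cells than in naive B cells, 6 adjusted over the list alone, and a median of 4.66 (adjusted p = 2.60e-05, adjusted p = 0.172 with an estimated correlation), which was 3.10 with rows having at least 1 value per group. DEFA1 rose by 8.71, CAMP by 7.64 and CTSG by 4.66, and BPI, at 5.25, did not pass (adjusted p = 0.0973). Monocyte markers had 4 of 13 higher, with 8 higher and 1 lower adjusted over the list alone and a median of 1.46 (adjusted p = 0.000369, adjusted p = 0.172 with an estimated correlation). IL1B rose by 7.70 and CSF3R by 2.02. The erythroid markers HBB and HBA1, which encode globin chains, rose by 5.85 and 4.37, 2 of 5 measured and 3 adjusted over the list alone, with a median of 1.90 (adjusted p = 0.0267, adjusted p = 0.529 with an estimated correlation). With rows having at least 1 value per group, that list had a median of 1.03 and an adjusted p of 0.0762, the highest over the alternatives at the preset correlation (lowest 0.0109). These markers differed on the same plasma cell arrays as the secretory lists. Among immediate early genes CD69 fell by 4.72 and IER5 fell by 3.51, also adjusted over the list alone, and the list's median of 0.42 was above 0 while its mean of -0.11 and its camera direction were below (adjusted p = 0.902). NR4A3, at -3.54, did not pass (adjusted p = 0.172).

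SLPI rose by 7.22 against naive B cells (SE 1.47), and the element annotated as COX15 by 8.69 (SE 0.61). GPR18, NIBAN3, S1PR1, RALGAPB and NARF fell, with differences of -7.18, -6.50, -6.11, -6.08 and -6.08, of which RALGAPB and NARF rest on clone annotation that was not checked. MYC had a difference of -0.01 that did not pass. The count of 274 genes was 126 without plasma cell replicate 1, 62 without plasma cell replicate 2, 50 without naive B cell replicate 1 and 29 without naive B cell replicate 2. It was 157 with rows having at least 1 value per group or with treat, 424 with single elements and 445 with array weights.

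Both plasma cell comparisons shared 172 genes past the threshold in the same direction, 90 higher and 82 lower, and 0 in opposite directions. Independent lists of these sizes would share 4.68 higher and 3.73 lower among the 3487 genes tested. In 100 simulations of unchanged groups that shared the plasma cell arrays, the highest overlap was 1 gene and the median 0. Unchanged groups yield few calls to share, so this overlap does not tell how much of the 172 the shared arrays produce. Log2 differences of the comparisons correlated across genes at 0.837, against 0.498 in the simulations, and their covariance of 1.93 exceeded the simulated 0.363 by 1.57. The simulations held no effect of the repeat number, which the same-numbered arrays could share. Part of the overlap beyond that of independent lists may come from the shared arrays, which were too few to split. The overlap was 109 with only the 4 arrays compared in each, 111 with rows having at least 1 value per group and 273 with single elements. It was 85 without mature B cell replicate 2, 95 without plasma cell replicate 1, 39 without plasma cell replicate 2, 44 without naive B cell replicate 1 and 28 without naive B cell replicate 2.

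Between mature bone marrow B cells and naive blood B cells MS4A1 differed by 0.06 (95% interval -2.01 to 2.13) and PAX5 by 0.95 (-1.11 to 3.01), and neither passed. Other genes of the B cell list had larger differences that also did not pass, among them CD83 at -2.87 (-4.30 to -1.44), CD72 at 2.24 (-1.43 to 5.91) and CD180 at 1.40 (0.30 to 2.50). With limma, 0 genes passed the threshold, and 221 of 3487 had an unadjusted p below 0.05. The largest difference among named genes was that of NR4A3, an immediate early nuclear receptor, at -10.78 (SE 1.34, adjusted p = 0.154), with means of -0.79 ± 0.46 in mature and 9.99 ± 0.37 in naive B cells (SD, n = 2 arrays per group).

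Immediate early genes as a list had lower ratios in mature bone marrow B cells, with a median of -1.25 and 16 of 21 members below 0 (adjusted p = 2.94e-08, adjusted p = 0.172 with an estimated correlation, fry adjusted p = 0.0659), and a median of -0.83 without mature B cell replicate 1. Over all genes 0 members passed, and 4 were lower adjusted over the list alone. ATF3, a stress-response transcription factor, had a difference of -6.02 (SE 0.55, adjusted p = 0.154) and HSPA1A, a heat shock chaperone, of -3.33 (adjusted p = 0.348). Erythroid markers as a list had higher ratios in mature bone marrow B cells, with a median of 1.72 (adjusted p = 0.0115, adjusted p = 0.498 with an estimated correlation, fry adjusted p = 0.108). HBB had a difference of 5.55 (SE 0.70, adjusted p = 0.154) and HBA1 of 3.34, with 0 of 5 past the threshold over all genes and 3 higher adjusted over the list alone. That list had an adjusted p of 0.0931 without mature B cell replicate 2 and 0.0507 with rows having at least 1 value per group, in a range from 0.00282 to 0.0931 over the alternatives. Of the 3 immunoglobulin genes 0 passed over all genes and 2 were higher in mature bone marrow B cells adjusted over the list alone, IGHM with a difference of 1.59. Among other named genes BCL6 had a difference of -1.65, DUSP5 of -2.85 and IGLL1 of 2.48, all short of the threshold. The 12 lists past the threshold only in plasma cell comparisons, among them B cell genes with a median of 0.28 (adjusted p = 0.174) and plasma cell genes at 0.59 (adjusted p = 0.0813), are drawn in the plot of list medians. Without mature B cell replicate 1, 35 genes passed, 30 higher and 5 lower in mature bone marrow B cells, and without plasma cell replicate 1 or 2, 1 gene did in each case. A gene with a log2 change of 4 was recovered in 56.1% of simulated cases, so a count of 0 does not exclude such differences.

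**Figure D3:**
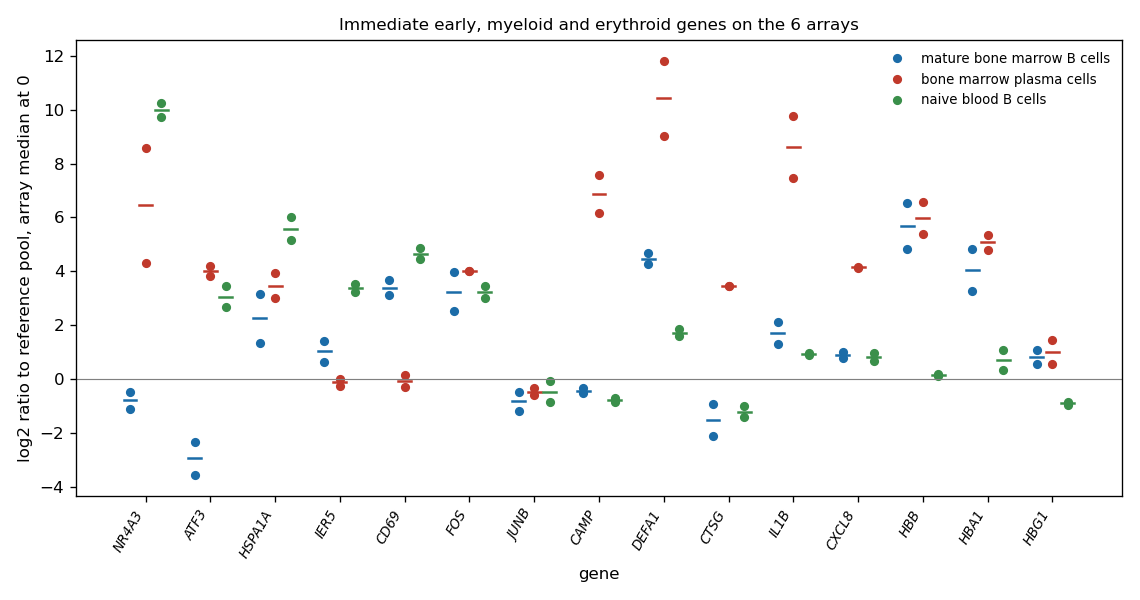
Log2 ratio to the reference pool (vertical axis, array median at 0) of 15 immediate early, myeloid and erythroid genes (horizontal axis), with 1 point per array and a bar at the mean of the 2 arrays of each group; FOS and JUNB were added after their values were seen. HBB had means of 5.69 in mature B cells, 5.99 in plasma cells and 0.14 in naive B cells, and CAMP had means of -0.43, 6.87 and -0.77.

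With fry, which tests whether a list's genes move 1 way on balance, 22 of the 28 list tests past the camera threshold also passed. The 6 that did not were the immediate early list (adjusted p of 0.0735 in plasma against mature B cells and 0.0659 between the B cell groups), the ribosomal list (0.133 and 0.0735 in the plasma cell comparisons) and the erythroid list (0.0605 in plasma against naive B cells and 0.108 between the B cell groups). In 5 further tests fry alone passed: NF-kB targets, interferon response and stromal markers in plasma against mature B cells, stromal markers in plasma against naive B cells, and immature B cell markers between the B cell groups.

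The other 16 tested lists passed in no comparison with camera, with adjusted p of 0.0562 or more and medians between -0.98 and 1.28. Their medians are given for plasma against mature, plasma against naive and mature against naive cells in that order. They were -0.21, 0.15 and 0.22 for MHC class I presentation, 0.00, 0.25 and 0.10 for cell cycle genes, 0.32, 0.16 and -0.10 for NF-kB targets and 0.46, 0.18 and -0.11 for oxidative phosphorylation. Glycolysis genes had 0.01, 0.22 and 0.09, proteasome genes -0.12, -0.04 and 0.06, BCL2 family genes -0.12, 0.35 and -0.11, and interferon response genes -0.02, 0.22 and 0.12. Chemokine receptors and adhesion molecules had 0.25, -0.15 and -0.03. For cell types, medians were 0.68, -0.07 and -0.49 for memory B cells, -0.98, -0.40 and 0.39 for immature B cells and -0.42, -0.61 and 0.25 for germinal centre B cells. T cell markers had -0.11, 0.50 and 0.36, NK cell markers 0.65, 1.01 and 0.26, platelet markers 1.28, 0.63 and 0.19, and stromal markers 0.46, 1.27 and 0.41. Median, mean and camera direction were not all of 1 sign in 18 of the 90 list tests, with 0.681 as the lowest adjusted p among them. In plasma against mature B cells these were the cell cycle, proteasome, BCL2 family, chemokine receptor and T cell lists. In plasma against naive B cells they were the MHC class I, immediate early, oxidative phosphorylation, glycolysis, proteasome, BCL2 family, interferon, memory, immature and germinal centre lists. Between the B cell groups they were the unfolded protein response (median 0.08), glycolysis and platelet lists. Single members did pass in some of these lists: CCL3, a chemokine, rose by 3.93 and 4.11 in plasma cells against mature and naive B cells, PDK1, a kinase that restrains pyruvate oxidation, by 3.67 and 3.68, and TRIM22, an interferon-induced gene, fell, at -4.78 and -4.68.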

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

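Bounds for the tests below were set before the list values were seen, but after single members (CAMP, CTSG, HBB, HBA1 and NR4A3) had been seen. Exceptions, chosen after their results were seen, are the test of a tissue effect and that of a shared background as the whole of the granulocyte difference. The tissue test was first made on the median of plasma against mature B cells (1.20, interval 0.37 to 2.40), which was read as excluding that effect. It was then replaced by the median of plasma against naive B cells, which leaves the effect open. Also chosen after the values were seen was the rule, applied to every test, that an explanation counts as excluded, or as met, only where a 95% interval lies wholly outside, or inside, the range it needs. Intervals of medians resample list members, which are not independent, and those of shares are exact binomial.

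Immediate early genes drew attention because the plasma cell difference depended on the B cell group: the list's median was 1.20 against mature and 0.42 against naive B cells, and the test of mature against naive B cells gave a median of -1.25 (camera adjusted p = 2.94e-08, adjusted p = 0.172 with an estimated correlation, fry adjusted p = 0.0659). A single aberrant array is argued against, since the highest median with 1 of the 4 B cell arrays left out was -0.83 (interval -1.21 to -0.36). A pattern carried by 1 repeat alone is too, since the higher median within a repeat was -0.96 (interval -1.20 to -0.76). A shift common to the arrays of a repeat cancels in these differences, so the test could not show it. Monocytes among the naive B cells would have lowered the monocyte markers in this comparison, whose median was 0.18 (interval 0.08 to 0.30). A tissue effect shared by both bone marrow populations would put plasma cells below naive B cells too and cannot be told apart from other causes, because the median there was 0.42 with an interval from -0.94 to 0.95, with CD69 and IER5 lower in plasma than in naive B cells (-4.72 and -3.51) and NR4A3 and ATF3 higher in plasma than in mature B cells (7.24 and 6.96). Against naive B cells NR4A3 had a difference of -3.54 (limma adjusted p = 0.172), while ATF3 had means of 4.01 in plasma and 3.06 in naive B cells. A response of the cells to isolation and a tissue or cell state difference in mature B cells alone remain open and untested, because tissue, population and preparation change together here.

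Erythroid markers drew attention for the same reason: their median was 0.49 in plasma against mature and 1.90 in plasma against naive B cells, and it was 1.72 in mature against naive B cells (camera adjusted p = 0.0115, adjusted p = 0.498 with an estimated correlation, fry adjusted p = 0.108). Erythroid cells or their RNA in the bone marrow samples may be a source, but 60% of the 5 measured markers were higher by at least 0.5 (interval 14.7% to 94.7%), between the bounds set for and against. The globin genes HBB, HBA1 and HBG1 had differences of 5.55, 3.34 and 1.72, while KLF1 had 0.20 and TFRC, which other dividing cells also express, -0.98. Of markers without values on all 6 arrays, EPB42 had 4.64 on 1 mature and 1.86 on 1 naive B cell array, GATA1 had 0.37 on 1 mature and 0.71 and -0.01 on the naive arrays, and CA2 had 1.76 and 0.85 against 3.28 and 2.60. In plasma cells, EPB42 had 2.78 on 1 array, GATA1 had 1.60 and 1.38, and CA2 had 0.36 on 1 array. With 5 markers these explanations cannot be told apart from a globin-specific source, and no biological explanation was tested.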

How the results depend on the processing

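Array weights and ratios limited to 6 were tried after the data were seen, and mature B cell replicate 2, whose removal was planned, was picked out again then because the mature B cell duplicates correlated least: without it the count of 214 was 90, and that of 0 between mature and naive B cells stayed 0. All 274 genes called between plasma and naive B cells kept their direction in every setting compared gene by gene, and all 214 called between plasma and mature B cells did except with rows having at least 1 value per group (212). The genes were called on these same arrays, so kept directions were largely given beforehand. For plasma against mature B cells the count of 214 was 342 with quantile normalization, 123 with only the 4 arrays compared, 351 with single elements, 896 by size without a test and 46 to 313 with 1 array left out. For plasma against naive B cells the count of 274 was 157 with rows having at least 1 value per group, 157 with treat, 445 with array weights, 424 with single elements, 994 by size without a test and 29 to 291 with 1 array left out. For mature against naive B cells the count of 0 was 1 with quantile normalization, 1 with only the 4 arrays compared, 4 with ratios limited to 6, 248 by size without a test and 0 to 35 with 1 array left out. The overlap of 172 was 111 with rows having at least 1 value per group, 109 with only the 4 arrays compared, 273 with single elements and 28 to 179 with 1 array left out. Of the 28 list tests past the threshold, 25 stayed past it with rows having at least 1 value per group, and 0 did with an estimated correlation. That last setting uses only the 3 residual degrees of freedom, so its count of 0 decides little about the lists. Fewer arrays also leave fewer degrees of freedom, and for the remaining settings the cause was not tested. Among named genes 0 called values changed sign, and 230 values with an array left out and 58 in other settings lost the threshold, while 31 and 63 came past it. With the repeat number as a replicate block the counts were 257, 291 and 0, the overlap 200 and the list tests 29. Deviations of same-numbered arrays correlated at 0.162 for plasma and mature, 0.318 for plasma and naive and 0.414 for mature and naive cells, and repeat 2 arrays lacked more values, so the number may mark a shared batch, which 2 numbers and the labels do not settle. Within each repeat alone all 214 and all 274 genes kept their direction. Their selection on these same arrays largely ensures that, so it says little about a batch. A group left with 1 array was assumed to vary like the others, and list tests on rows with at least 1 value per group used ranked statistics. With 2 arrays per group, array weights had to be equal within a group, so they could weigh only whole groups and not single arrays. Signal over background is not given in the sources used here, so its limit on weak elements is unknown.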

Other observations

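Groups of heat shock and sterol synthesis genes were picked after the 221 genes with an unadjusted p below 0.05 between mature and naive B cells had been seen, and their bounds were set before the remaining members were seen. For granulocyte precursor genes the bounds were set before the list values but after CAMP and CTSG had been seen, the test of a shared background as the whole of their difference was chosen after its result was seen, and the need for an interval was added to every verdict after the values were seen. Heat shock genes, which encode chaperones, had a median of -1.22 in mature against naive B cells, with 10 of 11 measured members below 0, 8 of them at an unadjusted p below 0.05 and 0 past the adjusted threshold. HSP90AA1 had a difference of -3.44 and BAG3 of -2.99, and HSPA1A, also in the immediate early list, of -3.33. For the same list plasma cells had a median of -1.21 against naive B cells, with 2 members past the threshold, and of 0.72 against mature B cells, with 0. Sterol synthesis genes had a median of -0.72 in mature against naive B cells, with 7 of 10 below 0 and 0 past the adjusted threshold, and medians of 0.33 in plasma against mature and -0.21 in plasma against naive B cells, with members on both sides of 0 and 1 past the threshold in each. In mature against naive B cells IDI1 had a difference of -2.59 (adjusted p = 0.292) and SQLE of -1.98 (adjusted p = 0.416), while SREBF2, a regulator of the pathway, had 3.41 (adjusted p = 0.350).

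A response shared by each gene class may lie behind these values, and the members not among the genes first noticed were used to test it. Of the 3 such heat shock genes 66.7% were lower (interval 9.43% to 99.2%), and of the 4 such sterol synthesis genes 50% were lower (interval 6.76% to 93.2%). So few genes decide nothing, and both remain hypotheses.

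Granulocyte precursor genes were higher on the plasma cell arrays, a pattern for which granulocyte precursors or their RNA among the isolated cells may be a source. That source stays open, because the share of markers tested largely restates the pattern and its interval reaches below the bound of 75%: 100% of 7 (interval 59.0% to 100%) were higher by at least 1 in plasma cells than in naive B cells, LTF by only 1.00 and DEFA1, at 10.43 ± 1.96 in plasma cells, by 8.71, and 0 of them belong to another fixed list. A single aberrant plasma cell array is argued against, since the lower median with 1 plasma cell array alone was 4.25 (interval 1.51 to 6.95). So is a background at an equal level in both bone marrow populations as the whole of the difference. The median in plasma against mature B cells was 4.54 (interval 1.91 to 5.96). That median restates the pattern, so a shared background at a higher level in the plasma cell samples stays open. A shared part also stays open at a median of 0.31 in mature against naive B cells (interval -0.33 to 0.71), with 4 markers higher and 3 lower. Among them DEFA1 had means of 4.48 ± 0.30 in mature and 1.72 ± 0.18 in naive B cells. Of markers without values on all 6 arrays, MPO, an abundant transcript of early precursors, decides nothing. Its ratios of -0.09 and 1.16 in plasma cells lay on both sides of 0.61 and 0.30 in mature B cells and 0.41 on 1 naive B cell array. In the monocyte list SERPINA1 (3.75 and 8.75 in plasma cells, 3.28 on 1 mature and 1.08 on 1 naive B cell array) and TREM1 (3.31 and 3.86, 1.99 on 1 mature array, 1.15 and 0.13) were higher in plasma cells. CSF1R had 1.26 and 1.68 in plasma cells, 0.96 and 0.27 in mature B cells and 0.58 on 1 naive array. THBS1 had -0.35 on 1 plasma cell array, 0.11 and -0.05 in mature B cells and -0.09 on 1 naive array. The labels used here describe no gate that would remove such cells, and no biological explanation was tested.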
